A study of Mus musculus with 4 samples.

How the data were processed

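Non-cardiomyocyte cells were isolated from the ventricles of male mice, per the labels' protocols. The mice were 8 weeks old at the start, the left coronary artery was ligated, and mice with an ejection fraction above 45% at day 2 were excluded. Hearts were taken at 3 months. The tissue was digested with collagenase IV and dispase, passed through a 40 µm strainer, freed of dead cells and erythrocytes, and sorted for Live/Dead-negative, Calcein-positive cells, of which about 8000 were loaded per channel of a droplet instrument with a 3′ single-cell kit. By the labels all mice carried Tcf21iCre with a Tomato reporter, and the TTg-MI mice also the MGTH2A transgene. The labels gave 2 libraries for Sham, 1 for Ctrl-MI and 1 for TTg-MI.

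The authors deposited whole-number UMI counts per gene and cell, a raw and a filtered matrix per library, with no normalization. Per the submitters' processing notes, Cell Ranger 5.0.0, Seurat and R 3.6.3 were used, with the genome builds mm10 and GRCm38; the alignment settings are not given in the sources used here. The raw matrices held 6265, 10768, 12050 and 7535 cells for Sham 1, Sham 2, Ctrl-MI and TTg-MI, with 57674921, 79430821, 88308751 and 65328405 UMIs. The filtered matrices were checked against the raw ones and hold exactly the cells with more than 800 and fewer than 5000 genes and less than 10% mitochondrial UMIs, with 0 values changed. They held 5137, 9349, 8099 and 6182 cells, with a median of 3147, 2126, 3048 and 2782 genes and 3.96%, 3.12%, 3.49% and 4.03% mitochondrial UMIs per cell. The reporter transcript is among the genes, so its sequence was part of the reference. Whether a transgene sequence was part of it is not given in the sources used here.

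The filtered matrices were used for all main results. Doublets were scored per library with scrublet in scanpy 1.11.5 and removed: 70 (1.36%), 160 (1.71%), 207 (2.56%) and 128 (2.07%) cells. The remaining 28202 cells were scaled to 10000 UMIs, log-transformed and reduced to 30 principal components of 2000 variable genes. Leiden clustering at resolution 1 on 15 neighbours gave 30 clusters (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9). A cluster was given the class name of 1 of 17 marker lists when at least 3 of its markers, and at least 40% of them, were detected in at least 20% of the cells, the mean score was at least 0.5 and the next best class scored no more than 85% of the best. A cluster whose leading genes held more markers of another class than of its own, or of low depth and with none of its markers in the lead, stayed unnamed. The 40% threshold was set after the data were seen. This named 11 classes, each called by its markers as similar to that cell type. The unnamed clusters 19 and 29 held 267 cells led by T and NK cell genes and 118 cells led by proliferation genes.

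The marker lists, 26 gene lists, tests and main alternatives were fixed before the data were examined. Raw counts were summed per library and class, and classes with at least 50 cells in every library were compared. Infarcted libraries (Ctrl-MI and TTg-MI) were compared with Sham by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter on low counts, 2 residual degrees of freedom, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation as an alternative, and adjusted over the lists of a class. Counts for list members are given adjusted over the list alone and over all genes. A fit of 3 groups, with 1 residual degree of freedom, was a secondary comparison.

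TTg-MI and Ctrl-MI, with 1 library each, were compared without a test outside the fit of 3 groups. A gene passed when the pair held at least 50 UMIs, differed at least 2-fold on the scale of TMM-normalised log2 CPM (counts scaled by the library total) with a prior count of 2, and differed by more than the Sham libraries. The median difference of each list was placed among 10000 random lists of equal size, each member drawn from the 50 genes on either side of it in mean expression, with bounds at percentile 2.5 and its mirror. The Sham pair was treated alike. Genes at least 2-fold beyond both Sham libraries in 1 of 2 equal random parts of the Ctrl-MI cells were compared between TTg-MI and the other part. Shares of cells with a UMI were taken after thinning each cell to 1500 UMIs. Levels in CPM are on library totals where given with Poisson intervals, in the check of labels, in low-gene barcodes and in the last part. The same holds for Rad51ap1 outside endothelial-like cells and for Rpl29 in fibroblast-like and macrophage or monocyte-like cells. The comparison of genes nearer to Sham used library totals too. Other levels are on TMM-scaled totals. Intervals are exact 95% binomial or Poisson intervals, and a level of 0 is set against a floor of 3 counts.

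Genes were named by a rule. For infarction against Sham these were the 10 largest changes in each direction past the threshold in each of the fibroblast-like, endothelial-like and macrophage or monocyte-like classes, with both infarcted libraries beyond both Sham libraries. Where none passed, the 5 genes with the lowest p in each direction were taken. For TTg-MI against Ctrl-MI they were the 10 largest differences in each direction past the rule of size. Y-linked genes, Xist, numbered gene models and immunoglobulin or T cell receptor genes were counted but not named. Members of the gene lists, the 4 factors and 9 fibroblast genes could be named in addition. Positions are those of GENCODE vM21 on GRCm38, the build of the submitters' notes, where 20610 of 21002 genes had a position.

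The steps were tested on simulated data with the real means and library sizes, at 1 common dispersion per class for all genes. That dispersion came from the fit of infarcted against Sham libraries. It therefore holds the real differences between Ctrl-MI and TTg-MI and between the Sham libraries. Of planted 4-fold changes the edgeR step recovered 99%, 100% and 99% in fibroblast-like, endothelial-like and macrophage or monocyte-like cells, and of 2-fold changes 44%, 80% and 29%, with 6, 17 and 3 false calls among 14346, 12621 and 11439 genes. The rule of size recovered 51%, 55% and 46% of 2-fold changes and 99%, 99% and 98% of 4-fold changes, with 280, 72 and 184 unplanted genes passing among 13363, 11227 and 9872. All simulated genes of a class had the same spread, and recovery was not read separately for genes with few UMIs. The recovery rates therefore need not hold for real genes. In real fibroblast-like cells Comp was more than 4-fold higher in both infarcted libraries than in either Sham library. The edgeR step did not call Comp over all genes. The list percentile placed 5 of 100 unchanged lists outside its bounds, and 98, 100 and 97 of 100 lists shifted by 0.5 above them. Simulated genes varied independently, so these rates need not hold for real lists, whose genes may vary together. For the real Sham pair 10 of 16 lists lay outside the bounds in fibroblast-like cells.

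The alternatives tried were DESeq2 1.42.0 and its size factors, no filter on low counts, cells of the raw matrix with 500 to 6000 genes and less than 10% mitochondrial UMIs, called doublets kept, 0.5 and 2 times the clustering resolution, equal cells and UMIs per library, each library left out in turn, other thresholds of the rule of size, prior counts of 0.5 and 5, library totals, another seed, and thinning to 3000 UMIs. Leaving out 1 Sham library in the comparison of genes nearer to Sham was added after the data were seen. Plots were drawn with matplotlib 3.10.9. The result for 1 gene is not reported here.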

Results

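Single-cell RNA libraries were prepared from the non-cardiomyocyte cells of mouse ventricles 3 months after a coronary artery was tied off, or after a sham operation. The series concerns the conversion of resident heart cells into cardiomyocyte-like cells in a heart with an old infarct, and its hearts fall into 3 groups. Sham was represented by 2 libraries, Ctrl-MI by 1 library and TTg-MI by 1 library. By the labels, Sham and Ctrl-MI mice carried Tcf21iCre with a Tomato reporter. Tcf21iCre is a Cre recombinase tied to Tcf21, a transcription factor gene of resident cardiac fibroblasts. TTg-MI mice carried in addition the MGTH2A transgene, named for the transcription factors Mef2c, Gata4, Tbx5 and Hand2. The deposited filtered count matrices held 5137 and 9349 cells for Sham replicates 1 and 2, 8099 for Ctrl-MI and 6182 for TTg-MI. Their unique molecular identifiers (UMIs, each 1 captured transcript) summed to 50365927, 68611166, 75422651 and 53226563, with a median per cell of 9763, 5182, 9178 and 7322. Values for 4 libraries are given below in this order, Sham 1, Sham 2, Ctrl-MI and TTg-MI. Nothing in the labels states that the Sham libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical. On the infarcted side that spread also holds the difference between the Ctrl-MI and TTg-MI genotypes.

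The labels were checked on the reporter and on the 4 factors in fibroblast-like cells. The Tomato reporter transcript stood at 96.3 CPM of the summed class counts (95% Poisson interval 93.0 to 99.6), 3.77 (3.02 to 4.65), 33.4 (31.9 to 35.0) and 32.2 (30.3 to 34.3). Endothelial-like cells, read as background, held 10.9, 7.01, 6.71 and 5.27 CPM, so the reporter was not above background in the fibroblast-like cells of Sham 2. The reporter label of Sham 2 was therefore not borne out by these values, which do not tell why. Its group was read from its title, and that of the other libraries from their treatment label. Every spread within Sham rests on this library and Sham 1. Mef2c stood at 63.8, 72.8, 91.5 and 96.9 CPM, Gata4 at 49.0, 33.5, 36.3 and 41.6, and Hand2 at 58.3, 46.8, 56.8 and 60.8. Tbx5 was scarce, with 58, 34, 115 and 80 UMIs, or 1.67, 1.47, 2.21 and 2.57 CPM. The median log2 difference of the 4 factors between TTg-MI and Ctrl-MI was 0.06, at percentile 66.1 of random lists matched on expression. The cardiomyocyte genes behaved alike, with a median of 0.05 at percentile 66.9, and 15 of 27 measured members were higher in TTg-MI. Myh6, the adult myosin heavy chain of cardiomyocytes, stood at 3.37, 1.43, 1.64 and 2.70 CPM, and Tnnt2, cardiac troponin T, at 9.30, 7.36, 9.70 and 6.73. A 3′ count library may not read the transgene and reads the endogenous genes, so these values do not check the transgene label. All Poisson and binomial intervals cover counting error only.

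Fibroblast-like and endothelial-like cells together made up most of every library, and their proportions differed more between the 2 Sham libraries than between the infarcted ones. Fibroblast-like cells made up 53.3% of Sham 1 (exact 95% binomial interval 51.9 to 54.7), 17.5% of Sham 2 (16.7 to 18.3), 54.5% of Ctrl-MI (53.4 to 55.6) and 39.9% of TTg-MI (38.6 to 41.1). The Sham mean was 35.4% ± 25.3 (SD, n = 2), and both infarcted libraries lay within 1 SD of it. Endothelial-like cells made up 21.9%, 55.1%, 25.9% and 41.2%, against a Sham mean of 38.5% ± 23.5 (SD, n = 2). Macrophage or monocyte-like cells made up 7.05%, 16.5%, 8.41% and 7.85%, against a Sham mean of 11.8% ± 6.65 (SD, n = 2). B cell-like cells made up 2.47% and 2.02% of the Sham libraries, 1.19% of Ctrl-MI and 1.31% of TTg-MI, so both infarcted libraries lay below the Sham mean of 2.25% ± 0.313 (SD, n = 2) by more than its SD. The same held for smooth muscle-like cells, against a Sham mean of 1.575% ± 0.496 (SD, n = 2), for lymphatic endothelial-like cells, on 11, 23, 16 and 7 cells, and for cells left unnamed. It did not hold for unnamed cells with cells of the raw matrix, with called doublets kept or at 0.5 times the clustering resolution, under which no lymphatic endothelial-like class was named, nor a smooth muscle-like one at 0.5 times the resolution. Pericyte-like cells made up 6.14%, 0.947%, 2.45% and 3.70%, neutrophil-like cells 4.24%, 2.92%, 4.09% and 2.49%, and smooth muscle-like cells 1.22%, 1.93%, 0.71% and 0.859%. Clusters left unnamed held 1.48%, 1.502%, 1.27% and 1.19%, under a marker threshold set after the data were seen. No test of shares was run. Dissociation, a 40 µm strainer and a sort for Live/Dead-negative, Calcein-positive cells can set these shares, and the libraries also differed in depth.

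**Figure D1:**
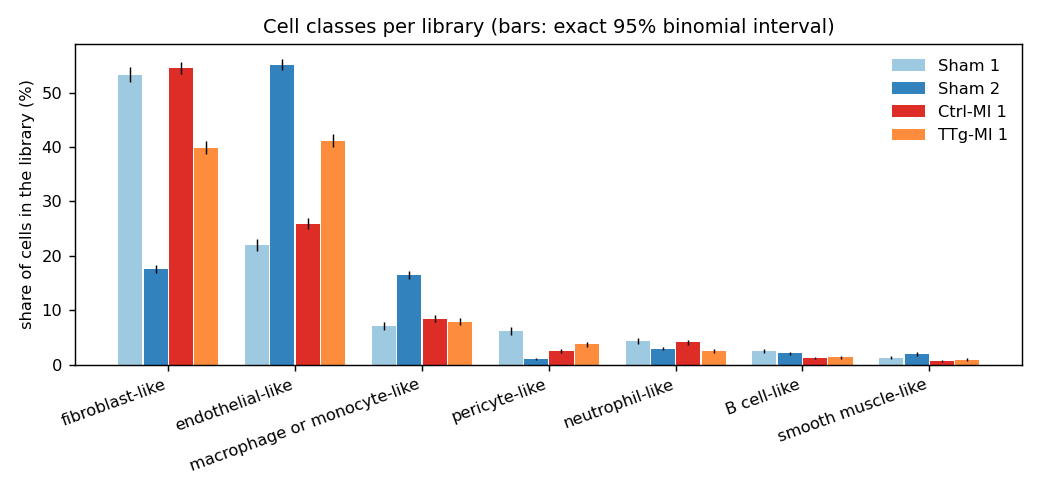
Share of cells (%, vertical axis) of 7 cell classes in each of the 4 libraries, as bars with exact 95% binomial intervals that cover counting error only. The fibroblast-like share ran from 17.5% in Sham 2 to 54.5% in Ctrl-MI, and the Sham libraries stood at 53.3% and 17.5%.

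Infarction was compared with sham operation in the classes with at least 50 cells in every library, taking Ctrl-MI and TTg-MI as 2 infarcted libraries against 2 Sham libraries. The infarcted libraries differ in genotype, so genes that changed after infarction but differ between these 2 libraries were harder to call. In fibroblast-like cells, 5 genes were higher after infarction and each was higher in both infarcted libraries than in both Sham libraries. Mmp3, the matrix protease stromelysin-1, stood at 12.2, 14.2, 113 and 126 CPM after TMM scaling, 9.09-fold higher (log2 3.18, SE 0.14, adjusted p = 0.00831, edgeR). Gabra3, a subunit of the GABA-A receptor, stood at 1.62, 1.07, 16.9 and 20.2 CPM, 13.5-fold higher (log2 3.75, SE 0.25, adjusted p = 0.0282). Mrap2, an accessory protein of melanocortin receptors, had 0 UMIs in both Sham libraries against 754 and 408 in the infarcted ones, at least 269.7-fold higher against a floor of 3 counts over the group (adjusted p = 0.0207). C1rb stood at 0.116, 0.0893, 49.6 and 42.0 CPM (422-fold, log2 8.72, SE 0.24, adjusted p = 0.00101). C1s2 had 4 and 0 UMIs in Sham against 1169 and 637 (log2 8.18, SE 0.48, adjusted p = 0.0207). C1rb and C1s2 are near-identical copies of the complement protease genes C1ra and C1s1, with which they can share reads, and their values are uncertain. C1ra stood at 212, 147, 107 and 149 CPM and C1s1 at 348, 193, 189 and 256, and neither passed the test. C1rb had 0 UMIs in both Sham libraries of endothelial-like, macrophage or monocyte-like and pericyte-like cells too. Its UMIs in Ctrl-MI and TTg-MI were 18 and 16, 13 and 14, and 18 and 19 there, not separated from free RNA.

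On the reference assembly GRCm38, Mmp3 spans chromosome 9, 7445822 to 7455975, and Mrap2 spans chromosome 9, 87144306 to 87184045, both on the plus strand. Gabra3 spans chromosome X, 72432681 to 72656848, on the minus strand. C1rb and C1s2 lie together on chromosome 6, at 124570294 to 124581171 on the plus strand and 124624625 to 124636085 on the minus strand. The edgeR test called 5 genes higher and 0 lower among 14527 tested, with 901 at an unadjusted p under 0.05, where DESeq2 called 114 higher and 53 lower. The edgeR count became 24 without Sham 1, 2 without Ctrl-MI and 13 without TTg-MI. Mrap2 and C1s2 lost the call without Ctrl-MI, and Gabra3 without Ctrl-MI, without TTg-MI and with cells of the raw matrix.

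Among the gene lists, late scar genes of fibroblasts were higher in the infarcted libraries and stress genes were lower. The mix of clusters differed too, and it was not separated from changes within cells. Cluster 9 held 28.9%, 27.9%, 9.23% and 6.42% of the class. Cluster 11 held 5.0%, 5.4%, 26.9% and 16.4%, and cluster 13 held 3.33%, 5.96%, 25.8% and 13.5%. Of 14 measured matrifibrocyte genes, which mark fibroblasts of a mature scar, 13 were higher, with a median log2 difference of 1.24. Comp, cartilage oligomeric matrix protein, stood at 54.7, 41.7, 1284 and 554 CPM, Chad, chondroadherin, at 4.20, 5.55, 53.1 and 9.03, and Fmod, fibromodulin, at 5.44, 13.3, 91.4 and 28.7. The list rose in camera (adjusted p = 1.21e-19), though the adjusted p = 0.314 with an estimated correlation. Of its members, 7 passed adjusted over the list alone (Comp, Chad, Fmod, Sfrp2, Omd, Clu and Ccn5) and 0 over all genes by edgeR. Matricellular and scar matrix genes rose too (20 of 24 higher, median 0.39, mean 0.92, adjusted p = 3.35e-10, and adjusted p = 0.479 with an estimated correlation). Postn, the matricellular protein periostin, stood at 148, 346, 953 and 514 CPM, and 2 members, Cthrc1 and Ddah1, passed adjusted over the list alone. Fibrillar collagen and crosslinking genes rose by a small median of 0.14 (17 of 26 higher, adjusted p = 2.7e-05, and adjusted p = 0.484 with an estimated correlation). Their 4 members past the threshold adjusted over the list alone were Col11a1, Lox, Loxl3 and P4ha3, while Col1a1 stood at 1171, 1534, 1529 and 1568 CPM. Contractile myofibroblast genes rose (13 of 15 higher, median 0.20, adjusted p = 0.00233, and adjusted p = 0.314 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. TGF-beta response genes rose (17 of 26 higher, median 0.10, adjusted p = 0.0160, and adjusted p = 0.484 with an estimated correlation), with Runx1 and Scx past the threshold adjusted over the list alone.

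Wnt pathway genes of fibroblasts also rose (11 of 13 higher, median 0.72, adjusted p = 4.05e-11, and adjusted p = 0.314 with an estimated correlation). The 6 that passed adjusted over the list alone were Wif1, Dkk3, Sfrp1, Sfrp2, Frzb and Axin2. All but Axin2, a target gene of the pathway, encode secreted antagonists of Wnt ligands or their relatives. Immediate early and heat shock genes, which dissociation of tissue also induces, fell in all 25 measured members (median −0.85, adjusted p = 8.7e-43, and adjusted p = 0.314 with an estimated correlation), 18 of them adjusted over the list alone. Fos stood at 1581, 1429, 819 and 496 CPM. Class II antigen presentation genes fell (7 of 7 lower, median −0.35, adjusted p = 0.00932, and adjusted p = 0.484 with an estimated correlation), as did nuclear oxidative phosphorylation genes (30 of 35 lower, median −0.10, adjusted p = 0.0389, and adjusted p = 0.610 with an estimated correlation). The cardiomyocyte genes fell (18 of 26 lower, median −0.45, adjusted p = 0.0476, and adjusted p = 0.621 with an estimated correlation), a direction that turned without Sham 1, with cells of the raw matrix, with called doublets kept and at 0.5 times the clustering resolution. In Sham 1 their transcripts were raised: Myl2 stood at 14.8, 3.82, 2.97 and 3.01 CPM, and Tnni3 at 10.3, 1.56, 1.43 and 1.63. The remaining lists did not pass, with adjusted p = 0.127 for the 4 factors, 0.0773 for resting fibroblast genes, 0.309 for interferon response, 0.140 for the cytosolic ribosome, 0.0773 for the mitochondrial genome and 0.481 for the cell cycle, whose median of −0.02 and mean of 0.03 differ in sign. Without Sham 1, 6 lists passed in place of 10.

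**Figure D2:**
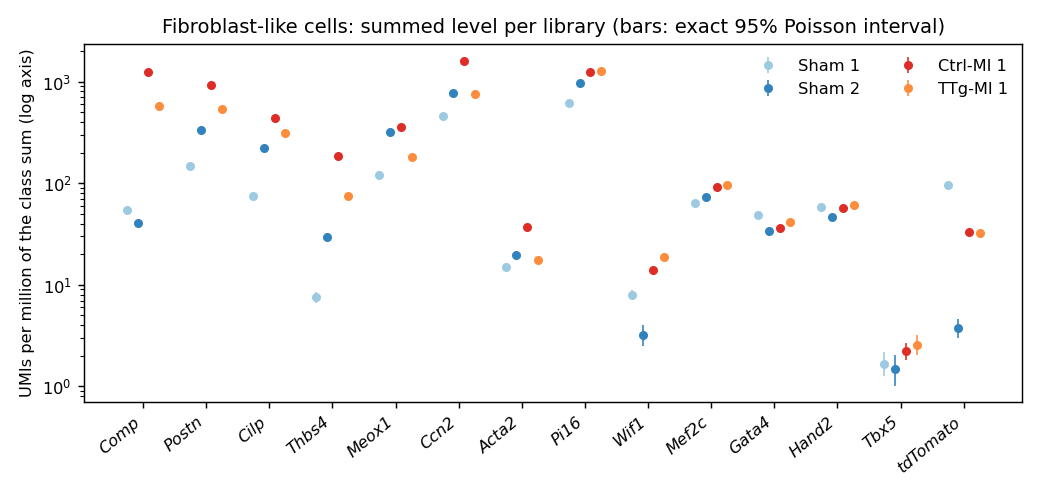
CPM of the summed fibroblast-like counts (vertical axis, log scale) for 14 genes, 1 point per library with its 95% Poisson interval. Comp stood at 54.7 and 40.6 in the Sham libraries, 1258 in Ctrl-MI and 581 in TTg-MI, while Mef2c, Gata4, Hand2 and Tbx5 each differed less than 2-fold between the 4 libraries.

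In endothelial-like cells, 3 genes were higher and 1 was lower in the infarcted libraries. Esm1, a proteoglycan of endothelial tip cells, stood at 27.2, 22.6, 74.9 and 65.7 CPM, 2.86-fold higher (log2 1.52, SE 0.14, adjusted p = 0.0347, edgeR). Rad51ap1, which acts in DNA repair by recombination, stood at 6.56, 4.65, 31.5 and 36.9 CPM, 6.41-fold higher (log2 2.68, SE 0.22, adjusted p = 0.0169). Pianp, a membrane protein that binds the receptor PILR-alpha, had 2 UMIs over both Sham libraries against 210 over the infarcted ones, a ratio of 139 (counting interval 37.9 to 1153, adjusted p = 0.0169). The transcript of the ribosomal protein gene Rpl29 fell, from 486 and 692 CPM in Sham to 149 and 171 (log2 −1.88, SE 0.19, adjusted p = 0.0413). Rpl29 has near-identical processed copies with which it can share reads, and its value is uncertain. It was not called but lower in fibroblast-like (467, 737, 148 and 153 CPM on library totals) and macrophage or monocyte-like cells (579, 929, 184 and 195) too. Infarction was not separated from any other difference between the Sham and infarcted mice. The positions on GRCm38 were chromosome 13, 113209659 to 113218098 for Esm1, chromosome 6, 126923050 to 126939587 for Rad51ap1, chromosome 6, 124996694 to 125003096 for Pianp, and chromosome 9, 106429454 to 106431568 for Rpl29. The test covered 12812 genes, of which 644 had an unadjusted p under 0.05, and DESeq2 called 31 higher and 26 lower. The count of 4 became 218 without Sham 1, 45 without Sham 2, 18 without Ctrl-MI and 16 without TTg-MI. Esm1 lost the call at 0.5 times the clustering resolution and at equal cells and UMIs per library, and Rpl29 at 0.5 times the clustering resolution.

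Endothelial-like cells of the infarcted libraries had lower inflammation, class II and stress genes. Inflammation and adhesion genes fell (11 of 13 lower, median −0.64, adjusted p = 4.23e-08, and adjusted p = 0.275 with an estimated correlation). Vcam1, Icam1 and Cxcl1, which recruit leukocytes, passed adjusted over the list alone, with Icam1 at 152, 115, 77.6 and 72.2 CPM. Class II antigen presentation genes fell (10 of 10 lower, median −0.57, adjusted p = 1.13e-07, and adjusted p = 0.281 with an estimated correlation), and immediate early and heat shock genes fell (21 of 25 lower, median −0.50, adjusted p = 5.22e-22, and adjusted p = 0.275 with an estimated correlation). Arterial genes fell (11 of 16 lower, median −0.23, adjusted p = 0.00239, and adjusted p = 0.281 with an estimated correlation), as did interferon response genes (16 of 22 lower, median −0.23, adjusted p = 0.0113, and adjusted p = 0.666 with an estimated correlation), a direction that turned without Sham 2. Cytosolic ribosome genes fell in all 26 members by a median of 0.16 (adjusted p = 2.13e-05, and adjusted p = 0.569 with an estimated correlation), and mitochondrial genome genes in 10 of 13 members (median −0.09, adjusted p = 0.0174, and adjusted p = 0.666 with an estimated correlation), a direction that turned without Sham 1. Angiogenic tip and hypoxia genes rose (11 of 17 higher, median 0.14, adjusted p = 0.0237, and adjusted p = 0.405 with an estimated correlation). Esm1 and the basement membrane collagen gene Col15a1 rose adjusted over the list alone, whereas Vegfa, a growth factor induced by hypoxia, fell, at 36.6, 35.7, 22.8 and 21.2 CPM. Venous and endocardial genes did not pass as a list (adjusted p = 0.0587) although 8 members passed adjusted over the list alone, 3 higher (Plvap, Lrg1 and Ednrb) and 5 lower (Nr2f2, Vcam1, Npr3, Cytl1 and Tmem108). Capillary genes (adjusted p = 0.0688), endothelial-to-mesenchymal genes (0.352), nuclear oxidative phosphorylation (0.643) and the cell cycle (0.643) did not pass.

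In macrophage or monocyte-like cells 0 genes passed the edgeR test among 11671, with 866 at an unadjusted p under 0.05, while DESeq2 called 26 higher and 122 lower. The lowest adjusted p was 0.05001, for Pianp, at 1.12, 0.626, 26.02 and 19.3 CPM. The other genes with the lowest p among those higher after infarction were Comp (0.842, 0.626, 19.8 and 9.36 CPM, adjusted p = 0.0594), AC168977.1 (0.0594), Ifi213 (0.0769) and Cd209f (0.115). Comp was far higher in fibroblast-like cells, and its level here was not separated from free RNA. Among those lower were Tnf, a central inflammatory cytokine (91.0, 96.4, 33.5 and 28.1 CPM), Pmaip1, Dusp2 and Apold1, all with adjusted p = 0.0562. The count became 229 without Sham 1, 74 without Sham 2, 3 without Ctrl-MI and 4 without TTg-MI.

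Stress genes were the gene group with the clearest difference in these cells. Immediate early and heat shock genes fell in all 25 measured members (median −1.16, adjusted p = 2.72e-65), and this call held with an estimated correlation (adjusted p = 0.0295). All but Btg2, 24 members, passed adjusted over the list alone, and Fos stood at 1272, 1255, 584 and 545 CPM. Resident macrophage genes rose (13 of 16 higher, median 0.42, adjusted p = 1.27e-07, and adjusted p = 0.396 with an estimated correlation), as did complement and efferocytosis genes (12 of 14 higher, median 0.28, adjusted p = 3e-04, and adjusted p = 0.327 with an estimated correlation). Lyve1 (109, 165, 422 and 240 CPM), Gas6 and the scavenger receptor gene Stab1 (443, 481, 782 and 711) passed adjusted over the list alone. Recruited monocyte and inflammatory genes fell (11 of 18 lower, median −0.48, adjusted p = 2.09e-05, and adjusted p = 0.327 with an estimated correlation). Plac8, Il1b and Tnf were lower and Chil3 was higher adjusted over the list alone, with Il1b at 688, 453, 239 and 318 CPM. Cytosolic ribosome genes (26 of 26 lower, median −0.22, adjusted p = 9.85e-05, and adjusted p = 0.532 with an estimated correlation), nuclear oxidative phosphorylation genes (33 of 35 lower, median −0.16, adjusted p = 0.00982, and adjusted p = 0.767 with an estimated correlation) and cell cycle genes (14 of 17 lower, median −0.32, adjusted p = 0.0177, and adjusted p = 0.396 with an estimated correlation) fell. Interferon response did not pass (adjusted p = 0.953), and its median of 0.10 and mean of −0.04 differ in sign. Class II (adjusted p = 0.741), lipid-associated macrophage (0.318) and mitochondrial genome genes (0.152) did not pass. The largest cluster of this class was cluster 2 in Sham 1, with 50.7% of it, and cluster 21 in Sham 2, Ctrl-MI and TTg-MI, with 42.1%, 55.0% and 45.7%.

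Among the smaller classes, B cell-like and pericyte-like cells held called genes, named here after their values were seen. In B cell-like cells 3 genes rose and 3 fell among 6461 by edgeR. The matrix genes Bgn (39.5, 22.7, 109 and 165 CPM, 4.49-fold, adjusted p = 0.0162) and Sparc (68.8, 85.9, 188 and 201 CPM, log2 1.32, adjusted p = 0.0410) were higher, as was 1 immunoglobulin gene that was counted but not named by rule. The neutrophil genes S100a8 (146, 349, 19.7 and 0 CPM, adjusted p = 0.0132) and S100a9 (215, 398, 34.0 and 5.21 CPM, adjusted p = 0.00655) and the ribosomal protein gene Rpl29 (859, 1421, 269 and 248 CPM, adjusted p = 0.00655) were lower. B cells are not a usual source of Bgn, S100a8 or S100a9. Rpl29 was the 1 gene called in pericyte-like cells, lower at 311, 495, 93.7 and 111 CPM among 9554 genes (adjusted p = 0.00485). In neutrophil-like cells 0 of 7074 genes passed by edgeR (521 at an unadjusted p under 0.05, 12 by DESeq2), and in smooth muscle-like cells 0 of 6565 (470 and 29). With 1 library left out the counts ran from 17 (without Ctrl-MI) to 97 (without Sham 1) in B cell-like, from 1 (without TTg-MI) to 72 (without Sham 2) in pericyte-like, from 32 (without Ctrl-MI) to 86 (without Sham 2) in neutrophil-like and from 0 (without TTg-MI) to 334 (without Sham 1) in smooth muscle-like cells. The B cell-like and pericyte-like counts were 0 with called doublets kept.

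TTg-MI was then compared with Ctrl-MI, the comparison that bears on the transgene. Each group had 1 library, so the pair was compared by size, and the only test between them is a fit of 3 groups that borrows its spread from the Sham pair. A gene passed a rule of size when the pair held at least 50 UMIs, differed at least 2-fold and differed by more than the 2 Sham libraries did. In the class sums of fibroblast-like cells, genes of the mature scar were lower in TTg-MI and genes of resting fibroblasts were higher. The mix of clusters differed too, and it was not separated from changes within cells. From Ctrl-MI to TTg-MI, cluster 11 went from 26.9% to 16.4% of the class and cluster 13 from 25.8% to 13.5%. Cluster 15, led by resting fibroblast genes, went from 9.04% to 27.3%. Of the 14 late scar genes 13 were lower in TTg-MI, 6 of them at least 2-fold, with a median log2 difference of −0.85 below all 10000 random lists (percentile 0), where the Sham pair differed by 0.27 (percentile 99.9). Chad was 5.88-fold lower (counting interval 5.21 to 6.66). The ratio of TTg-MI to Ctrl-MI was 0.432 (0.425 to 0.439) for Comp and 0.314 (0.293 to 0.337) for Fmod. Matricellular genes were also lower (20 of 24, median −0.40, percentile 0), but the Sham pair differed more, by 0.77 (percentile 100). Among them Spp1, osteopontin, stood at 18.6, 74.6, 404 and 90.7 CPM and Ccn2, a connective tissue growth factor, at 457, 792, 1647 and 718. TGF-beta response genes were lower (17 of 26, median −0.28, percentile 0, Sham pair 0.19), including Runx1 (8.09, 13.4, 77.6 and 34.1 CPM) and Scx (2.02, 2.76, 26.2 and 8.05). Immediate early and heat shock genes were lower as well (21 of 25, median −0.48, percentile 0, Sham pair 0.03 at percentile 17.7), as were nuclear oxidative phosphorylation genes by a small margin (median −0.14, percentile 1.42, Sham pair 0.10). Resting fibroblast genes were higher (21 of 24, median 0.41, percentile 100, Sham pair −0.33 at percentile 0), with Lpl, lipoprotein lipase, at 2531, 1669, 1001 and 2158 CPM. Collagen genes as a list lay within the range of random lists (median −0.01, percentile 80.2), with Col1a1 at a ratio of 1.03 (1.01 to 1.04), and the contractile genes lay at −0.08 (percentile 17.0), although Acta2, smooth muscle actin, passed the rule at 15.1, 19.95, 38.2 and 16.8 CPM.

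The Wnt pathway list lay at −0.02 (percentile 52.7), with Dkk3 lower in TTg-MI (34.9, 38.8, 169 and 82.1 CPM) and Wif1 not (7.98, 3.29, 14.2 and 18.1). Interferon response (median 0.09, percentile 86.1), class II (−0.05, percentile 26.8), cytosolic ribosome (−0.32, percentile 2.81), mitochondrial genome (0.08, percentile 97.3) and cell cycle genes (−0.11, percentile 17.0) lay within the range of random lists. Of 16 lists, 6 lay outside the bounds of percentile 2.5 and its mirror for the TTg-MI and Ctrl-MI pair, and 10 did for the Sham pair. For 5 lists the infarcted pair lay outside and differed by more than the Sham pair. The fibroblast-like class was led by cluster 15 in Sham 1 (38.8%) and TTg-MI (27.3%), cluster 14 in Sham 2 (39.0%) and cluster 11 in Ctrl-MI (26.9%).

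**Figure D3:**
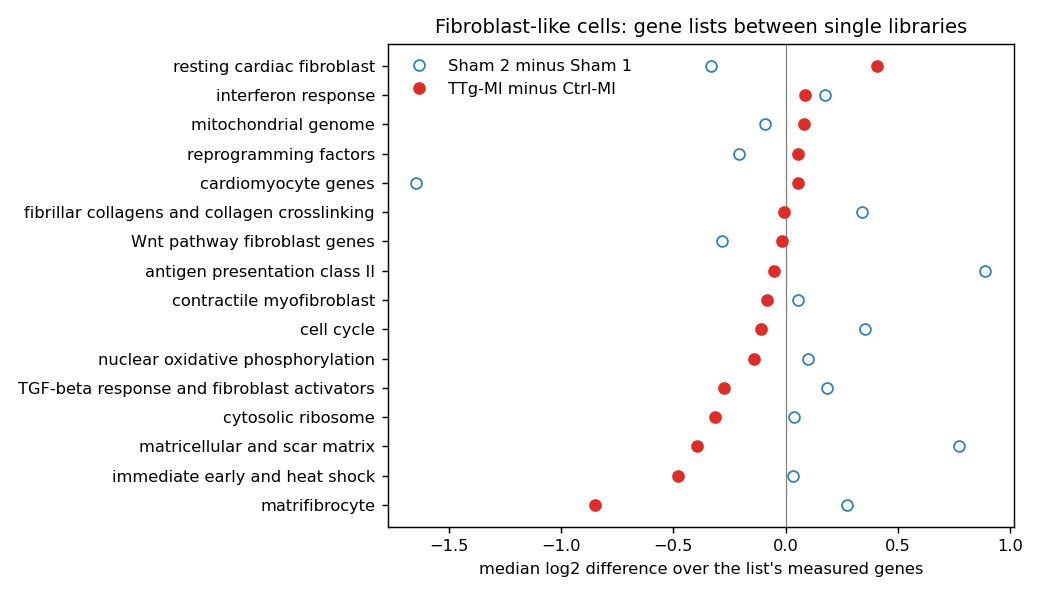
Median log2 difference (horizontal axis) of each gene list in fibroblast-like cells between TTg-MI and Ctrl-MI (filled red points) and between Sham 2 and Sham 1 (open blue points). Late scar genes lay at −0.85 between the infarcted libraries and 0.27 between the Sham libraries, and resting fibroblast genes at 0.41 and −0.33.

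Among single genes of fibroblast-like cells, 121 passed the rule of size as higher and 221 as lower in TTg-MI, of 13353 with enough UMIs. With library totals in place of TMM scaling the median over all genes moved to 0.09 and the split became 178 higher and 173 lower. The largest differences downward were in Cxcl13 (76.1-fold, counting interval 34.8 to 208), Cxcl10, Reln (13.5-fold, 8.40 to 23.0), Gsc, Ccl5, Mpzl2 (8.53-fold, 4.75 to 16.8), Pappa2 and Chad. Bst1 had 64 UMIs in Ctrl-MI and 2 in TTg-MI (20.5-fold, 5.44 to 173). Col2a1, the collagen of cartilage, had 53 UMIs in Ctrl-MI and 0 in TTg-MI, at least 10.6-fold lower. The largest differences upward were in Dct, Nxpe2, Onecut2, Hba-a1, Kcng4 (6.05-fold, 4.35 to 8.56), Chrm3, Apba2, Kcnip1 (4.58-fold, 3.72 to 5.66), Tenm4 (4.43-fold, 3.59 to 5.50) and Retnla. The potassium channel genes Kcng4 (4.26, 3.55, 0.904 and 5.47 CPM) and Kcnip1 (9.56, 7.42, 2.44 and 11.2) stood in TTg-MI near their Sham levels. For 6 of these 20 genes over 80% of the UMIs lay in 10 cells (Dct, Hba-a1, Ccl5, Cxcl10, Col2a1 and Cxcl13). Chad lies on chromosome 11, 94565047 to 94569127, Reln on chromosome 5, 21884454 to 22344702, Kcng4 on chromosome 8, 119623854 to 119635680, Kcnip1 on chromosome 11, 33629339 to 33993152, and Tenm4 on chromosome 7, 96171246 to 96911093. In simulated data with no difference in mean between the infarcted libraries other than in planted genes, 280 unplanted genes passed the rule, against the 342 observed. The simulated spread already held the real difference between Ctrl-MI and TTg-MI, so the 280 are not a count free of it.

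The share of fibroblast-like cells with a UMI of 9 fibroblast genes was compared after thinning each cell to 1500 UMIs. Thinning left out 1, 3, 49 and 4 cells. The share was lower in TTg-MI than in Ctrl-MI for 8 of the 9 genes. Pi16, among these 8, belongs to the list of resting fibroblast genes, which as a list was higher in TTg-MI. Comp was seen in 2.19%, 1.93%, 38.2% (exact 95% binomial interval 36.7 to 39.6) and 18.0% (16.5 to 19.6) of cells, against 0.821%, 0.281%, 6.32% and 2.56% of endothelial-like cells. Postn was seen in 6.67%, 19.1%, 33.0% and 20% (endothelial-like 0.821%, 0.882%, 5.57% and 3.06%), and Meox1, a transcription factor of activated fibroblasts, in 12.3%, 29.99%, 32.8% and 18.4% (endothelial-like 8.49%, 9.73%, 12.9% and 9.62%). Ccn2 was seen in 30.8%, 49.3%, 64.4% and 41.7% (endothelial-like 4.01%, 2.63%, 9.43% and 3.098%), Cilp in 4.96%, 16.4%, 23.6% and 17.3% (endothelial-like 0.274%, 0.221%, 2.36% and 1.16%), and Thbs4 in 0.259%, 0.933%, 4.37% and 2.20% (endothelial-like 0%, 0.04%, 1.66% and 0.33%). Acta2 was seen in 1.89%, 2.61%, 3.83% and 2.37% (endothelial-like 0.639%, 3.17%, 0.652% and 1.03%) and Pi16, a marker of adventitial fibroblasts, in 40.1%, 61.8%, 63.9% and 58.6% (endothelial-like 16.6%, 16.8%, 18.0% and 17.1%). Wif1, at 0.519%, 0.187%, 0.353% and 0.747% (endothelial-like 0%, 0%, 0.05% and 0.041%), was the exception. The endothelial-like share, read as background, was lower in TTg-MI than in Ctrl-MI for all genes but Acta2, and in Sham 2 that of Acta2 exceeded the fibroblast-like share. For Meox1, Ccn2, Acta2 and Pi16 the TTg-MI value lay between the values of the 2 Sham libraries, and for the other genes it lay above both. Without thinning the shares for Comp were 5.15%, 4.47%, 57.9% and 30.9%, for Postn 20.5%, 36.2%, 58.4% and 39.9%, and for Meox1 45.7%, 78.7%, 72.6% and 58.4%. The median depth was 12875, 14582, 12017 and 12971 UMIs in fibroblast-like cells and 4271, 3752, 3832 and 4225 in endothelial-like cells. The reporter was seen in 11.9%, 0.498%, 4.49% and 3.49% of fibroblast-like cells after thinning.

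In endothelial-like cells, class II genes were higher in TTg-MI than in Ctrl-MI, and genes of the mesenchymal list were lower. Class II genes were higher in 9 of 10 members (median 0.72, percentile 100, Sham pair 0.05 at percentile 76.5), with Cd74, the invariant chain, at 114, 187, 69.8 and 114 CPM. Macrophage or monocyte-like cells held these transcripts at far higher levels, and free RNA was not subtracted from class II genes in any class. Endothelial-to-mesenchymal genes were lower in 13 of 16 (median −0.25, percentile 0.04, Sham pair −0.06), with Postn at 5.31, 7.06, 35.4 and 16.9 CPM. Postn and the collagen genes of this list are abundant in fibroblast-like cells, and free RNA was not subtracted from the list. Nuclear oxidative phosphorylation genes lay at −0.10 (percentile 1.55), and venous genes at −0.17 (percentile 0.5), where the Sham pair differed by −0.56. The other lists lay within the range of random lists: interferon response −0.06, immediate early and heat shock 0.02, ribosome −0.11, mitochondrial genome 0.01, cell cycle −0.03, capillary −0.09, arterial −0.04, angiogenic tip −0.11 and inflammation −0.11. The endothelial-like class was led by cluster 4 in Sham 1 (23.9%), Sham 2 (42.9%) and Ctrl-MI (30.8%) and by cluster 0 in TTg-MI (31.9%). Of the 13 lists, 4 lay outside the bounds for this pair and 6 for the Sham pair. Among single genes 59 passed the rule as higher and 66 as lower of 11308, or 72 and 60 with library totals. In simulated data, whose spread held the real difference of this pair, 72 unplanted genes passed it. Nxpe4 had 1 UMI in Ctrl-MI against 479 in TTg-MI (ratio 346, counting interval 61.8 to 13700), with 96.6 and 45.3 CPM in the Sham libraries. It spans chromosome 9, 48162023 to 48400025. Nxpe2, within that span, stood at 1.81, 2.27, 0.275 and 2.30 CPM in fibroblast-like cells. At both genes Ctrl-MI, whose label gives no transgene, stood apart from the other libraries. Zbtb16, nearby at 48654297 to 48836222, went the other way in endothelial-like cells, at 4.33, 2.16, 18.7 and 4.38 CPM. The cause was not tested. The interferon-induced GTPase genes Iigp1 (350, 227, 169 and 518 CPM, 3.07-fold, 2.90 to 3.25) and Gbp6 (3.11-fold, 2.495 to 3.90) were higher, with Serpina1e, Serpina1d, Hba-a2, Il4i1, Olfr655, Hap1 and H19. Lars2, the mitochondrial leucyl-tRNA synthetase, was lower at 2310, 1604, 1620 and 469 CPM (3.45-fold, 3.35 to 3.56), with the leukocyte adhesion genes Sele and Selp, the neutrophil genes S100a8 and S100a9, and Thbs1, Ltbp2, Ecrg4, Zbtb16 and Serpina1b. S100a8 and S100a9 were lower in TTg-MI in fibroblast-like and macrophage or monocyte-like cells too, and were not separated from free RNA. H19, Selp and Sele rested on few cells, and H19 turned in direction at 0.5 times the clustering resolution. The Serpina1 family and the hemoglobin genes share reads with near-identical copies and are uncertain.

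In macrophage or monocyte-like cells, interferon response and class II genes were higher in TTg-MI. Interferon response genes were higher in 19 of 22 members (median 0.54, percentile 100, Sham pair −0.01 at percentile 34.2), with Iigp1 at 19.9, 20.2, 40.6 and 65.9 CPM and Ifit3 at 11.6, 8.23, 9.07 and 15.9. Cxcl10, by contrast, was lower, at 68.3, 75.1, 19.99 and 6.57. Class II genes were higher in 11 of 11 (median 0.34, percentile 99.99, Sham pair −0.30), with Cd74 at 14363, 8276, 8143 and 13875 CPM. Recruited monocyte genes were lower in 13 of 18 (median −0.24, percentile 0.2, Sham pair −0.03). Oxidative phosphorylation genes (−0.24, percentile 0), cell cycle genes (−0.22, percentile 1.30) and lipid-associated genes (−0.28, percentile 0.265) were lower too, where the Sham pair differed by 0.24, 0.24 and 0.58. Resident macrophage (−0.10), complement (−0.09), immediate early and heat shock (−0.08), ribosome (−0.15) and mitochondrial genome genes (0.05) lay within the range of random lists, and 6 of 11 lists lay outside the bounds for this pair and 6 for the Sham pair. Among single genes 89 passed as higher and 74 as lower of 10029, or 109 and 61 with library totals. That total of 163 was below the 184 unplanted genes that passed in simulated data, whose spread held the real difference of this pair. Nxpe4 was higher (2 UMIs against 55, ratio 37.5, 9.90 to 317), as were Ddit4, a gene induced by stress and glucocorticoids (4.91-fold, 3.49 to 7.06), H2-Q6 (4.40-fold, 3.29 to 5.95, uncertain among its near-identical relatives), Siglech, Pde8b, Adamdec1, Abcc9, Ccl5, Cd207 and Ifit2. Htr1b, a serotonin receptor gene (27.6-fold, 11.6 to 85.9), Guca1a (20.2-fold, 9.07 to 55.8), Prg4, lubricin (16.4-fold, 10.4 to 27.5), Areg, Il1a, Saa3, Hba-a1, Hbb-bs and Hbb-bt were lower, and the 3 hemoglobin genes turned in direction at 2 times the clustering resolution. Alox15 had 120 UMIs in Ctrl-MI and 0 in TTg-MI, at least 27.8-fold lower. For 11 of these 20 genes over 80% of the UMIs lay in 10 cells (Ccl5, Cd207, Ifit2, Areg, Hbb-bs, Prg4, Il1a, Hba-a1, Hbb-bt, Saa3 and Alox15).

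Whether genes that differed between Ctrl-MI and Sham lay nearer to Sham in TTg-MI was read with a random split of the Ctrl-MI cells into equal parts. Genes at least 2-fold beyond both Sham libraries in 1 part of the Ctrl-MI cells were compared between TTg-MI and the other part. Levels were on library totals, which put the median of all genes 0.09 (log2) higher in TTg-MI than in Ctrl-MI fibroblast-like cells. Such a shift brings lower genes nearer to Sham in TTg-MI and takes higher genes farther from it. In fibroblast-like cells 261 of 292 higher genes lay nearer to Sham in TTg-MI (89.4%, exact 95% binomial interval 85.3 to 92.7), their median log2 difference from Sham being 2.00 in Ctrl-MI and 1.15 in TTg-MI. Of the lower genes 128 of 161 did (79.5%, 72.4 to 85.5), with medians of −1.31 and −0.52. With genes chosen in TTg-MI and read in Ctrl-MI, 66 of 161 higher genes lay nearer to Sham in Ctrl-MI (41.0%, 33.3 to 49.0), but 76.0% of lower genes did. In endothelial-like cells 58 of 68 higher (85.3%) and 62 of 108 lower genes (57.4%) lay nearer to Sham in TTg-MI, against 75.4% and 66.7% with the choice turned round. In macrophage or monocyte-like cells the values were 61 of 85 (71.8%) and 108 of 169 (63.9%), against 69.2% and 66.0%. Differences of a single library from the others can raise these shares whichever library the genes are chosen in, and genes are not independent replicates.

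A fit of all 3 groups was run as a secondary comparison, under the assumption that the single infarcted libraries vary like the 2 Sham libraries. In fibroblast-like cells 13 of 15183 genes rose in Ctrl-MI against Sham by edgeR. They included Comp (26.4-fold, adjusted p = 0.0221), Chad (10.9-fold, adjusted p = 0.0362), Scx, a transcription factor of tendon (11.0-fold, adjusted p = 0.0434), Col22a1, Col8a2, Dkk3, Chil1 and Atp6v0a4, beside the 5 genes named above for infarction. Against Sham, 2 genes rose in TTg-MI, C1rb and Mmp3 (9.56-fold, adjusted p = 0.0387). With DESeq2 size factors 2 genes in place of 13 and 1 in place of 2 were called. Between TTg-MI and Ctrl-MI 0 genes passed, with 375 at an unadjusted p under 0.05, 15 by DESeq2 and a lowest adjusted p of 0.886. In endothelial-like cells 10 genes rose and 3 fell in Ctrl-MI, among them Comp (7.89-fold, adjusted p = 0.00392) and Postn (5.55-fold, adjusted p = 0.009). Comp and Postn were higher in fibroblast-like cells of the same library, and these rises were not separated from free RNA. In TTg-MI 7 rose and 5 fell, among them the stress genes Atf3, Fosb and Hsph1, which were lower. Nxpe4 was the 1 gene called between TTg-MI and Ctrl-MI (adjusted p = 0.0468), and it lost the call with DESeq2 size factors. In macrophage or monocyte-like cells 1 gene, Prg4, rose in Ctrl-MI (adjusted p = 0.0154), and 0 passed between TTg-MI and Ctrl-MI by edgeR (253 at an unadjusted p under 0.05, 9 by DESeq2). The 2 genes that fell in TTg-MI, named after their values were seen, were AY036118 (4998, 5228, 2998 and 440 CPM) and Gm42418 (54028, 58143, 34139 and 11912), and with DESeq2 size factors 0 genes passed in these cells. Lars2 was among the endothelial-like genes that fell in TTg-MI. With no filter on low counts the endothelial-like calls of this fit, that of Nxpe4 included, were lost. A call against Sham in Ctrl-MI and none in TTg-MI does not show a difference between them.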

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

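All tests of explanations in this part were chosen after the result was seen.

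The raw matrix of Ctrl-MI held 2931 barcodes with no more than 800 genes, 24.3% of its barcodes, against 384 (6.13%), 575 (5.34%) and 343 (4.55%) in Sham 1, Sham 2 and TTg-MI. These barcodes lie outside the comparisons of the report, and they carried fibroblast transcripts above the level in such barcodes of Sham. The Tomato reporter stood at 88.8 CPM in them (95% Poisson interval 77.3 to 102), with hemoglobin genes left out, against 30.5, 4.90 and 16.0 in the low-gene barcodes of Sham 1, Sham 2 and TTg-MI and 25.3 in the kept cells of Ctrl-MI. Col1a1 stood at 672 CPM, against 333, 65.3 and 211, and below the 1077.5 CPM of the kept cells of Ctrl-MI.

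For these barcodes shallower sequencing of Ctrl-MI and free RNA in the droplets were weighed, and no biological explanation was tested. In 1 of the 3 largest classes, fibroblast-like cells, the median UMIs of Ctrl-MI were the lowest of the libraries (12017), and in macrophage or monocyte-like cells they were the highest (10014), which leaves shallower sequencing open. Free RNA would keep fibroblast and endothelial markers in the ratio of the kept cells. In Ctrl-MI fibroblast markers exceeded endothelial markers by 0.77 (log2) beyond that ratio, and they fell short of it in Sham 1, Sham 2 and TTg-MI (−2.46, −3.32 and −2.79). The excess lay between the bounds set for and against free RNA, which keeps it open. Among cells of the raw matrix an unnamed cluster held 1537 cells, 1336 of them from Ctrl-MI, with a median of 922 UMIs and 605 genes. Fibroblast was its best-scoring class, and its leading genes were Sftpc, Sftpa1, Sftpb, Cxcl15, Cxcl1, Gdf15, Cdkn1a, Atf5, Gsta3 and tdTomato. The surfactant gene Sftpc also led the dendritic-like cluster, and the source of surfactant transcripts was not tested. Shallower sequencing, free RNA and damaged fibroblasts cannot be told apart here.

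Of the 9 genes called between infarcted and Sham libraries in fibroblast-like and endothelial-like cells, 4 (C1rb, C1s2, Pianp and Rad51ap1) lie at 3 of 8 loci within 20 Mb of Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333), a locus in which Cre reporters are often placed; the labels do not give the site. Of 15184 tested genes 234 lie there, and a share of 0.0004 of 10000 draws of tested genes reached as many loci, a count made on the genes that showed the pattern. The 4 genes lie between 124570294 and 126939587, and genes more than 100 kb apart counted as separate loci. The draws do not allow for neighbours that change together, so the share may be too small. Pianp was higher in both infarcted libraries in all 3 classes. Rad51ap1 was so in endothelial-like cells alone, at 0.288, 0.606, 0.423 and 0.45 CPM in fibroblast-like and 3.21, 1.57, 2.04 and 1.68 CPM in macrophage or monocyte-like cells. The transcript of Gt(ROSA)26Sor itself, at 3.77, 2.20, 13.5 and 16.0 CPM in endothelial-like cells, was called higher in TTg-MI than in Sham by the fit of 3 groups (adjusted p = 0.04815), but not in the comparison of infarcted with Sham libraries.

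A different haplotype around the locus in the infarcted mice may account for these genes. Among 154 uncalled genes of the window 0 were shifted at least 2-fold one way in all 3 classes, against 30 of all 10724 uncalled genes. A share of 1.0 of 10000 random draws of uncalled genes reached that count. Any draw reaches 0, so the share decides nothing. Were infarction the cause, the genes might follow the late scar list between TTg-MI and Ctrl-MI in fibroblast-like cells, where C1rb and C1s2 lay at −0.25 and −0.23 and Pianp at −0.85 (median −0.245), against −0.85 for the list. Neither value excludes its explanation, since a haplotype need not shift many genes, or a gene in every class, and 3 genes are few. C1rb and C1s2 were also called by a test that favours genes with a small difference between the infarcted libraries. Their distance from the late scar list therefore decides nothing. A haplotype and infarction therefore cannot be told apart for C1rb, C1s2 and Pianp, and for Rad51ap1 infarction was not tested.

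Late scar genes were lower in TTg-MI than in Ctrl-MI fibroblast-like cells (median −0.85). These are class sums, and a different mix of clusters was not separated from lower levels within cells. With the endothelial-like level subtracted as free RNA, the median of 13 members was −0.71 against −0.73 before, which argues against free RNA as the whole cause. The Sham pair differed by 0.27 on the same list, but uninfarcted hearts hold no scar to vary in. The 4 factors differed by 0.0558 in the median, and a 3′ tag may miss the transgene. Variation between single mice, such as in infarct size, and the transgene therefore cannot be told apart with 1 library per group, and the hypothesis that the transgene lowers late scar genes stays untested.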

How the results depend on the processing

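Leaving out 1 Sham library in the comparison of genes nearer to Sham was added after the data were seen; the other alternatives were planned. Counts given below are of genes or lists, and where no construction of the alternative is named the cause was not tested. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The rule of size and the comparison of its lists could not be run without a library of either infarcted group, since each has 1.

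Genes called between infarcted and Sham libraries, in the order fibroblast-like, endothelial-like and macrophage or monocyte-like, numbered 97, 295 and 481 with no filter on low counts and 167, 57 and 148 with DESeq2. In B cell-like, neutrophil-like and smooth muscle-like cells they numbered 90, 154 and 209 with no filter and 2, 12 and 29 with DESeq2, and in pericyte-like cells 50 with no filter. In macrophage or monocyte-like cells the count was 1 with DESeq2 size factors, with called doublets kept and at 0.5 times the clustering resolution, and 35 at equal cells and UMIs per library. It was 2 in B cell-like cells with cells of the raw matrix and 0 with called doublets kept. In pericyte-like cells it was 0 with cells of the raw matrix, with called doublets kept and at 2 times the clustering resolution, and 3 at equal cells and UMIs, where smooth muscle-like cells had 7. With 1 library left out the counts ranged from 2 to 24 in fibroblast-like, 16 to 218 in endothelial-like, 3 to 229 in macrophage or monocyte-like, 17 to 97 in B cell-like, 32 to 86 in neutrophil-like, 1 to 72 in pericyte-like (22 to 72 where it moved) and 0 to 334 in smooth muscle-like cells (1 to 334 where it moved). A left-out library leaves 1 residual degree of freedom and a lone library assumed to vary like the other group.

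Lists called numbered 0, 0 and 1 with an estimated correlation, and 6 to 10 in fibroblast-like cells with 1 library left out. Lists whose direction turned are given with their adjusted p from camera, and with its range where 1 library was left out. In fibroblast-like cells cardiomyocyte genes turned higher with cells of the raw matrix (0.0425), called doublets kept (0.107), at 0.5 times the clustering resolution (0.0985) and without Sham 1 (7.42e-18 to 0.237). Resting fibroblast genes turned higher without Sham 1 and without Ctrl-MI (0.000276 to 0.822), cell cycle genes lower without Sham 1 and without Ctrl-MI (0.270 to 0.829), and ribosome genes higher without TTg-MI (4.84e-05 to 0.421). In endothelial-like cells venous genes turned higher at 0.5 times (0.0422) and 2 times the clustering resolution (0.128) and without Sham 1 (1.29e-07 to 0.872), and oxidative phosphorylation genes at 0.5 times the resolution (0.920) and without TTg-MI (0.254 to 0.828). Without Sham 1 mitochondrial genome genes turned higher (3.95e-07 to 0.565) and capillary genes lower (2.93e-06 to 0.456), without Sham 2 interferon (8.36e-10 to 0.269) and cell cycle genes (0.0124 to 0.752) turned higher, and without TTg-MI mesenchymal genes (0.162 to 0.939). In macrophage or monocyte-like cells interferon genes turned lower with cells of the raw matrix (0.588), called doublets kept (0.625) and without Sham 1, Sham 2 or TTg-MI (0.0145 to 0.864). Class II genes turned higher without Sham 1 and without Ctrl-MI (0.0358 to 0.334), and lipid-associated genes without Sham 2 (1.74e-06 to 0.999).

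In the fit of 3 groups, with Ctrl-MI against Sham, TTg-MI against Sham and TTg-MI against Ctrl-MI in this order, the counts with no filter were 255, 94 and 14 in fibroblast-like, 0, 0 and 0 in endothelial-like and 302, 262 and 64 in macrophage or monocyte-like cells. With DESeq2 they were 168, 73 and 15 in fibroblast-like and 56, 44 and 9 in macrophage or monocyte-like cells, and 4 between TTg-MI and Ctrl-MI in endothelial-like cells. With DESeq2 size factors they were 2 and 1 against Sham in fibroblast-like cells, 0 between TTg-MI and Ctrl-MI in endothelial-like cells, and 0 and 0 against Sham in macrophage or monocyte-like cells.

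Between TTg-MI and Ctrl-MI the rule of size passed 978, 521 and 663 genes at 1.5-fold, 544, 277 and 347 at 20 UMIs or more and 153, 42 and 48 at 200 UMIs or more, as those thresholds are wider or narrower. The contractile list turned to 0.00769 with library totals, H19 to −0.65 at 0.5 times the clustering resolution, and Hbb-bt, Hba-a1 and Hbb-bs in macrophage or monocyte-like cells to 0.55, 0.84 and 0.81 at 2 times the resolution. In these cells 5 lists in place of 3 lay outside and beyond the Sham pair at 0.5 and at 2 times the clustering resolution. The endothelial-like share of Ctrl-MI was 22.9% with cells of the raw matrix and 23.2% at 0.5 times the clustering resolution, where that of TTg-MI was 36.6%. The fibroblast-like share of Ctrl-MI was 45.9% with cells of the raw matrix and 53.3% with called doublets kept. Of all shares by group, 39 moved and 87 did not, and of the shares of fibroblast-like cells with a UMI 62 moved and 12 did not with thinning to 3000 UMIs or none. Unnamed cells moved to 15.1% of Ctrl-MI with cells of the raw matrix and to 7.82% of Ctrl-MI and 10.8% of TTg-MI at 0.5 times the resolution. With cells of the raw matrix smooth muscle-like cells moved to 0.247% of Ctrl-MI and 0.308% of TTg-MI, and erythroid-like cells with called doublets kept to 0.086% and 0.162%.

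Of genes higher than Sham in TTg-MI fibroblast-like cells, 41% lay nearer to Sham in Ctrl-MI. Of genes higher in Ctrl-MI by 1.5-fold, 70.8% lay nearer to Sham in TTg-MI in endothelial-like and 52.1% in macrophage or monocyte-like cells. Without 1 Sham library the range was 78% to 85.7% in fibroblast-like and 70.1% to 73.2% in endothelial-like cells, and 68.2% to 79.5% for genes lower in fibroblast-like cells. Of the other results, 51 of the alternatives for named macrophage or monocyte genes passed the threshold that none passed as reported, and for named fibroblast and endothelial genes 55 and 45 kept their call and 5 and 3 lost it. The depth of the smaller classes limits what they can show.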

Other observations

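The genes in this part were chosen after their values were seen, and their levels are given without a test apart from 1 call.

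Some of 11 genes of the circadian clock differed between the libraries of fibroblast-like cells, and Nr1d1, Nr1d2, Per1, Per2 and Cry1 did so by a larger ratio within Sham than between the infarcted libraries. Nr1d1, the clock repressor REV-ERB alpha, stood at 70.8, 11.8, 51.8 and 82.3 CPM in Sham 1, Sham 2, Ctrl-MI and TTg-MI, and Nr1d2 at 41.7, 14.1, 30.3 and 42.5. Dbp, an output gene of the clock, stood at 14.2, 7.02, 12.0 and 24.4, and Per1 at 19.2, 7.80, 8.80 and 18.7. Cry1 ran the other way, at 10.8, 31.8, 19.1 and 13.5, as did Per2, at 3.69, 11.7, 6.41 and 3.09. In these 6 genes Sham 2 lay at one end of the order and Ctrl-MI lay between Sham 2 and TTg-MI. Others went the other way: Tef (19.0, 18.2, 17.6 and 28.5), Npas2 (47.5, 44.96, 31.1 and 44.0) and Per3 (17.0, 13.2, 13.05 and 18.0) differed more between the infarcted libraries, and Clock (90.1, 96.6, 89.4 and 95.6) and Arntl (60.6, 70.6, 73.4 and 65.4) differed less than 1.5-fold over all 4. The labels give no time of day for the collection of the hearts.

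Smaller classes were seen in every library. Schwann-like cells made up 0.928%, 0.359%, 0.253% and 0.413%, dendritic-like cells 0.296%, 0.609%, 0.482% and 0.363%, erythroid-like cells 0.73%, 0.381%, 0.545% and 0.677%, and lymphatic endothelial-like cells 0.217%, 0.25%, 0.203% and 0.116%. Among fibroblast-like cells the noncoding transcript of the Gt(ROSA)26Sor locus stood at 18.9, 1.21, 11.4 and 12.2 CPM, in the same order of libraries as the Tomato reporter except for Ctrl-MI and TTg-MI. In endothelial-like cells it stood at 3.69, 2.13, 13.5 and 16.8 on library totals, or 3.77, 2.20, 13.5 and 16.0 after TMM scaling. There the fit of 3 groups called it higher in TTg-MI than in Sham.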
